A study of Vibrio parahaemolyticus RIMD 2210633 with 6 samples.

How the data were processed

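RNA sequencing was done on 6 libraries of Vibrio parahaemolyticus RIMD2210633, 3 given water and 3 given phage VpP2326 for 15 min. Per the labels' protocols, total RNA was extracted with a column kit and libraries were sequenced on an Illumina or an MGI instrument. The labels do not say which library ran on which instrument, name no step that removes ribosomal RNA, and do not say whether the kit marks strand.

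The deposited table holds, for each of 4742 genes, a read count and an FPKM value per library and a gene size, per the file headers. HTSeq 0.6.1 is named in the submitters' processing notes, which do not state its role. The aligner, genome build, annotation version and strand setting are not given in the sources used here. Without a known strand setting, reads from a gene and from an overlapping or antisense neighbour cannot be told apart. The counts as deposited were used for all tests. The deposited FPKM values, which divide each count by gene size and library total, were used only as a check: among genes with at least 500 counts they returned each library's summed count to within 1. Of the gene sizes, 96.2% are multiples of 3, so they are mostly coding lengths. Columns headed Control were taken as the water libraries, since the study has 2 conditions, and the number in a column name was matched to the replicate number in the labels.

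Genes are identified by locus tags, and 1453 rows also carry a symbol while 3289 carry the tag alone. No genome or annotation was used here, so no coordinates or product names are given, and functions are background knowledge of the symbol. A symbol is shared by several rows in 87 cases. Copies with near-identical sequence, such as the tuf genes and the 5S ribosomal RNA rows named rrf, could share reads, and so could the phage's own transcripts and related host genes, since the phage genome was not used here.

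Differential expression was tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults (minimum count 10, minimum total 15), which kept 4206 genes and left out 536, TMM scaling, robust glmQLFit and glmQLFTest, with phage against water as the single term. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and 1056 genes had an unadjusted p under 0.05. TMM factors lay between 0.983 and 1.012 and the common biological coefficient of variation was 6%. Levels are CPM, counts divided by the TMM library sizes, and errors of fold changes are standard errors. Fold values are from the fitted log2 fold changes. Total counts were 5642352 to 8753065 per library, and the spread between libraries of a group, which exceeded counting error, limits the precision as well. The procedure was tested on simulated counts for phage against water (4197 genes): edgeR recovered 40.8% of genes changed by 0.3 on the log2 scale, 68% at 0.5, 87.5% at 1 and 100% at 2, and called 0.15% of unchanged genes. Changes of 0.3 were thus more often missed than called in the simulation. It left 3970 genes unchanged, so fewer genes changed than were called in the data. Its adjusted threshold was therefore stricter, and recovery in the data may be higher.

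Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, for lists with at least 4 tested members. Of 52 lists fixed before the data were examined, 27 were tested, 7 had 1 to 3 tested members, and 18 had no member. The last were mostly defined by older locus tags, such as secretion systems, genomic islands, prophage, capsule and lateral flagella, and are not analysed here. After the data were examined, 9 lists by symbol were added. Some cover such systems. Others, such as fatty acid synthesis, cell division, RND efflux and pyruvate dehydrogenase, replace no list without members. With an estimated correlation, 0 of the 11 called fixed lists and 0 of the added lists passed. That form of camera takes its degrees of freedom from the 6 libraries, the preset form from the number of genes. Its p-values are therefore larger at any correlation.

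Named genes followed a rule fixed before the data were examined: the 8 largest rises and 8 largest falls among called genes with a symbol, non-overlapping libraries and a mean of at least 20 CPM in the higher group; the 3 largest of each with or without a symbol; up to 4 called members with the smallest p in each list; and a set of genes reported whatever their values. Of that set, no row carries the symbols aphA, ompU, ompK, ompA, lamB, tolC, tlh, tdhA or tdhS, and groEL was matched as groL and tdhA and tdhS as tdh. For the added lists the same number of members was named. Outside the rule, clpB, lon, grpE, clpX, clpA, clpP, ftsH, ndk, tmk, ahpF, VP_RS09420, VP_RS03945 and the genes of the closing observations were named after their values were seen. The symbols hutC, arcA and arcB can stand for genes outside the function of their list.

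Libraries of a group were compared before averaging. The chi-square of their counts over its degrees of freedom was 3.43 to 10.28 within groups, so no pair agreed within sampling noise. Shares of counts were compared by exact permutation tests. Alternatives were median-of-ratios and upper-quartile scaling, no filter and a filter at a mean of 10 CPM, the DESeq2 1.42.0 Wald test, the replicate number as a block, leaving out the 10 most abundant genes and the 5S rows from scaling, leaving out each library, and for lists the estimated correlation and fry.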

Results

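Transcript levels were measured by RNA sequencing in Vibrio parahaemolyticus strain RIMD2210633, a marine bacterium that causes seafood-borne gastroenteritis, after contact with the phage VpP2326. A mid-exponential culture in tryptic soy broth (OD600 of 0.6, 37 °C) was divided, and 100 µl of either water or phage was added for 15 min before RNA extraction. There were 3 water libraries and 3 phage libraries, which the series describes as biological copies. The labels do not say whether each came from a separate starting culture, so p-values measure the spread between these libraries. Total counts were 5642352, 8753065 and 8003158 in water 1 to 3 and 8299213, 8027864 and 5682270 in phage 1 to 3. Across genes, the Pearson correlation of log2 CPM (counts scaled to a common library total) was 0.992 to 0.995 within groups and 0.987 to 0.99 between groups, and genes are not independent replicates. The first principal component (45.8% of the variance) separated the groups. The second (19%) set water 1, at 12.6, apart from water 2 at -5.6 and water 3 at -7.7. The 12 rows named rrf, for 5S ribosomal RNA, held 0 counts in 5 libraries and 1 count in phage 2. A count of 0 allows these rows a share of up to 3.43e-05% to 5.32e-05% of the assigned counts, for counting error only. How reads shared by near-identical rows were counted is not given, so this does not bound the 5S RNA sequenced. The tmRNA gene ssrA took 2.43% ± 0.105 of the counts with water and 2.46% ± 0.324 with phage (n = 3 each, exact permutation p = 0.9, two-sided, smallest possible 0.1). The RNase P RNA gene rnpB took 1.51% ± 0.269 and 1.72% ± 0.0757 (exact permutation p = 0.4, n = 3 each).

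The design asks how the host transcriptome with phage differed from that with water. Of 6 tested genes listed for the synthesis of deoxynucleotides, the building blocks of DNA, 4 rose with phage (the list's camera adjusted p = 1.83e-10, and adjusted p = 0.0629 with an estimated correlation), as did a gene pair for DNA ligation and cell division. nrdA (VP_RS09395), which encodes the large subunit of aerobic ribonucleotide reductase, rose 11.9-fold, from 627 ± 14.1 to 7462 ± 165 normalised CPM (SD, n = 3 each). nrdG (VP_RS19675), for the activating enzyme of the anaerobic reductase, rose 11.3-fold from 11.7 ± 1.3 CPM, and nrdD (VP_RS19680), for that reductase itself, rose 5.51-fold to 2159 ± 64.9 CPM. nrdB (VP_RS09400), for the small aerobic subunit, rose 6.3-fold. yfaE (VP_RS09405), for a ferredoxin that helps to maintain the NrdB cofactor, rose 6.07-fold. ligA (VP_RS03920), the DNA ligase gene, rose 7.44-fold from 219 ± 6.3 to 1625 ± 27.9 CPM, and the row before it, zipA (VP_RS03915), for a protein that anchors the division ring to the membrane, rose 4.5-fold. The gene with the largest rise under the naming rule, VP_RS00075 (438 bases, listed without a symbol), went from 25.3 ± 4.58 to 614 ± 84.7 CPM, a 24.6-fold rise. ompW (VP_RS15710), for a small outer membrane protein, rose 3.95-fold. Together nrdA, nrdB, yfaE, nrdD, nrdG, zipA and ligA took 0.197% ± 0.00577 of all counts with water and 1.49% ± 0.0265 with phage (SD, n = 3 each), a sum over genes chosen for their rise and so not tested.

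**Figure D1:**
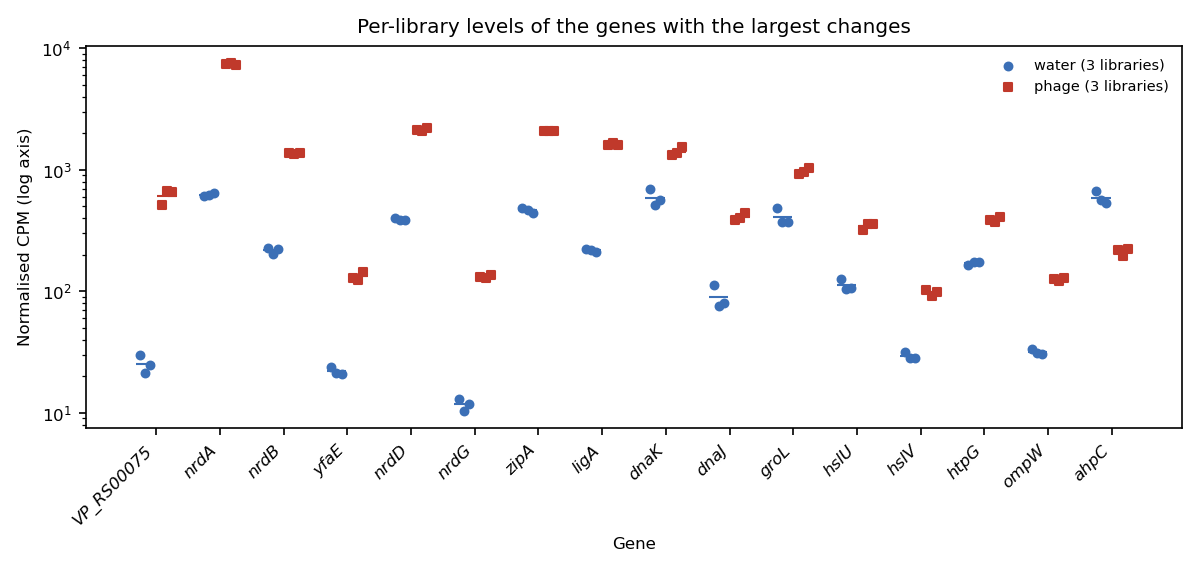
Normalised CPM (log axis) of 16 genes in each of the 3 water libraries (blue circles) and 3 phage libraries (red squares), with a short line at each group mean; groL is VP_RS14030. In every gene drawn the 3 phage libraries lie on one side of the 3 water libraries, with nrdA moving from a mean of 627 to 7462 and ahpC from 588 to 212.

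In edgeR's quasi-likelihood test, 603 of 4206 tested genes (14.3%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 365 were higher and 238 lower with phage. At least 2-fold changes were found in 56 genes, 53 of them higher and 3 lower, and the median size of the called changes was 0.33 on the log2 scale. The adjusted p was 2.3e-22 for nrdA (log2 fold change 3.57 ± 0.054 SE), 7.91e-18 for nrdG (3.50 ± 0.094), 1.57e-20 for ligA (2.89 ± 0.055) and 4.1e-07 for VP_RS00075 (4.62 ± 0.152). In 1242 genes (29.5%) the libraries of the groups did not overlap, against 10% by chance for 3 against 3. The number of calls depended on single phage libraries: without phage 1 it was 380 (114 lower) and without phage 2 it was 383 (120 lower). Without water 1, the library set apart on the second component, 755 genes were called.

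The members of the deoxynucleotide synthesis list that rose were nrdA, nrdB, nrdD and nrdG, 0 fell, and the list's median log2 fold change was 2.56. Adjusted over the list alone, 4 rose and 1 fell. ndk and tmk, for nucleoside and thymidylate kinases, had log2 fold changes of -0.19 and -0.08. The rows directly before and after these runs in the table were not called, with log2 fold changes from -0.34 to 0.40. Farther out, VP_RS09420, 3 rows after yfaE, rose 2.38-fold (edgeR adjusted p = 7.2e-13) and VP_RS03945, 5 rows after ligA, 2.18-fold (9.25e-09), both named after their values were seen. In the DNA replication list 3 of 15 members rose, ligA, dnaG and dnaA, and topA fell (camera adjusted p = 0.0616, and 4 rose and 1 fell adjusted over the list alone). dnaG (VP_RS01935), the primase gene, rose 1.3-fold. The calls of dnaA (1.14-fold higher) and topA (1.14-fold lower) were lost without phage 1 (adjusted p = 0.157 and 0.114) and without phage 2 (0.171 and 0.127). The call of dnaA was also lost without water 1 (0.0719), and that of topA without water 3 (0.0548). The DNA replication list itself passed without water 2 (adjusted p = 0.0382) and without water 3 (0.0101), and with all libraries its adjusted p = 0.606 with an estimated correlation. The list's median log2 fold change was 0.04 and its largest, 2.89, was that of ligA.

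**Figure D2:**
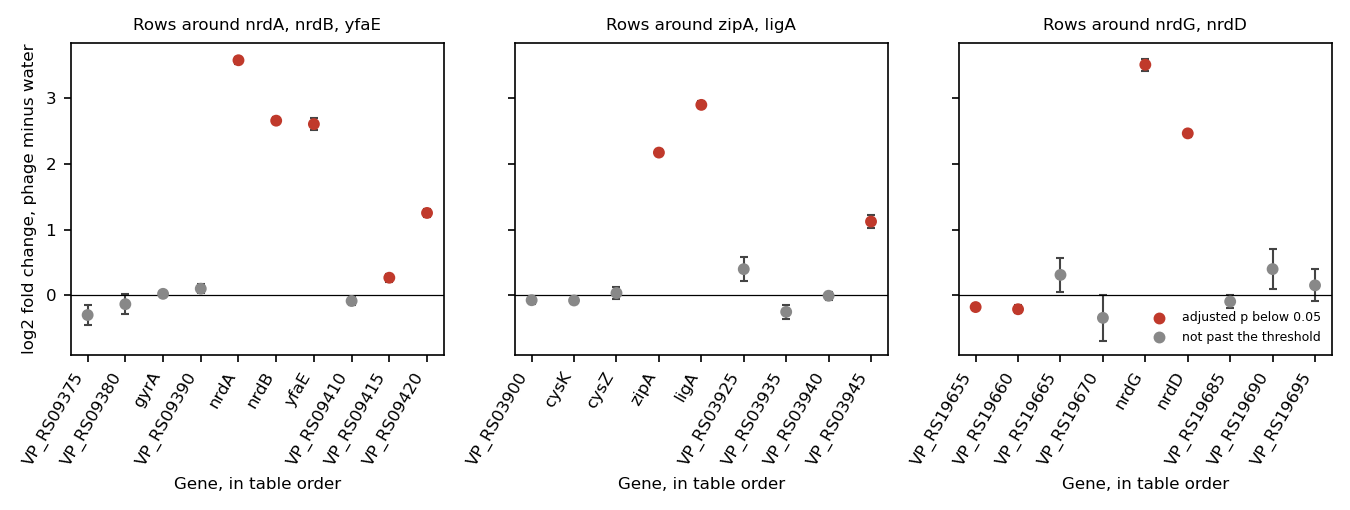
Log2 fold change (phage minus water, n = 3 each) of tested genes in table order around nrdA, nrdB and yfaE, around zipA and ligA, and around nrdG and nrdD; bars are standard errors and red marks an adjusted p below 0.05. The lead genes lie between 2.17 and 3.57 and the rows directly beside them between -0.34 and 0.40, while VP_RS09420 lies at 1.25 and VP_RS03945 at 1.12.

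Genes for heat shock chaperones, which refold damaged proteins, and for the ATP-dependent proteases HslUV and Lon rose with phage. Of the 15 tested members of the list of heat shock chaperones and proteases, 11 rose and 2 fell, with a median log2 fold change of 0.87. The protease genes clpP and ftsH were not called (log2 fold change -0.10 and -0.03). dnaJ (VP_RS03145), for a co-chaperone, rose 4.62-fold, from 90 ± 20.7 to 411 ± 27.9 CPM (edgeR adjusted p = 0.000166). hslV and hslU (VP_RS01225 and VP_RS01220), for the HslUV protease, rose 3.36-fold and 3.1-fold, and dnaK (VP_RS03140) rose 2.42-fold, from 588 ± 93.4 to 1418 ± 122 CPM. htpG rose 2.27-fold and hslO 1.71-fold. clpB (2.56-fold), lon (1.83-fold) and grpE (1.48-fold), named after their values were seen, rose as well. Of the genes with the symbol groL, for the GroEL chaperonin, VP_RS14030 rose 2.38-fold, from 410 ± 66.2 to 974 ± 51.3 CPM. The other, VP_RS16645, was 1.22-fold higher with overlapping libraries, and its call was lost without water 3, phage 2 or phage 3 (adjusted p = 0.0576, 0.0611 and 0.0721). The members that fell were clpX (1.14-fold) and clpA (1.12-fold), for unfoldases of the Clp proteases, and both calls were lost without phage 1 (adjusted p = 0.186 for clpX and 0.138 for clpA) and without phage 2 (0.142 and 0.161). That of clpA was also lost without water 3 (0.0886) and without phage 3 (0.0922). The list's camera adjusted p was 1.82e-13, and its adjusted p = 0.248 with an estimated correlation. Adjusted over the list alone, 11 members rose and 2 fell. Relative to the water group, the list's mean log2 level was 0.13, -0.09 and -0.04 in the water libraries and 0.79, 0.83 and 0.91 in the phage libraries, with water 1, the library apart on the second component, the highest of its group.

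Over the lists for ribosomal proteins, the respiratory chain, ATP synthase and the TCA cycle, 41 of 84 genes fell with phage and 0 rose, with a median log2 fold change of -0.23. Without phage 1 or without phage 2, 27 of them fell. Of 54 ribosomal protein genes, 21 fell and 0 rose, with a median log2 fold change of -0.18 (camera adjusted p = 4.81e-13). The list's adjusted p = 0.338 with an estimated correlation, 25 fell adjusted over the list alone, and 13 fell without phage 1. rplC (VP_RS01255) fell from 2569 ± 156 to 2048 ± 104 CPM (1.25-fold) and rpsS (VP_RS01275) 1.26-fold. Of 13 genes for NADH:quinone reductases and cytochrome oxidases, enzymes of the respiratory chain, 9 fell and 0 rose (median -0.30, camera adjusted p = 3.39e-07, and adjusted p = 0.263 with an estimated correlation). cydA and cydB (VP_RS05120 and VP_RS05125), for cytochrome bd oxidase, fell 1.31-fold and 1.3-fold, cyoA 1.28-fold and ccoP 1.23-fold. ybgE (VP_RS05135), listed 2 rows after that cydB, fell 1.47-fold. cyoC fell 1.37-fold, a call lost without water 3 (adjusted p = 0.0897) and without phage 1 (0.105). Of 7 ATP synthase genes, 6 fell (median -0.25, camera adjusted p = 6.02e-06, and adjusted p = 0.291 with an estimated correlation), and 3 fell without phage 2. atpE fell 1.27-fold and atpB 1.23-fold. Of 10 genes of the TCA cycle, 5 fell and 0 rose (median -0.27, camera adjusted p = 1.08e-05, and adjusted p = 0.248 with an estimated correlation). sdhA fell 1.29-fold and lpdA, for the dihydrolipoyl dehydrogenase also used by pyruvate dehydrogenase, 1.36-fold. Adjusted over the list alone, 10 respiratory chain, 7 ATP synthase and 8 TCA cycle genes fell.

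**Figure D3:**
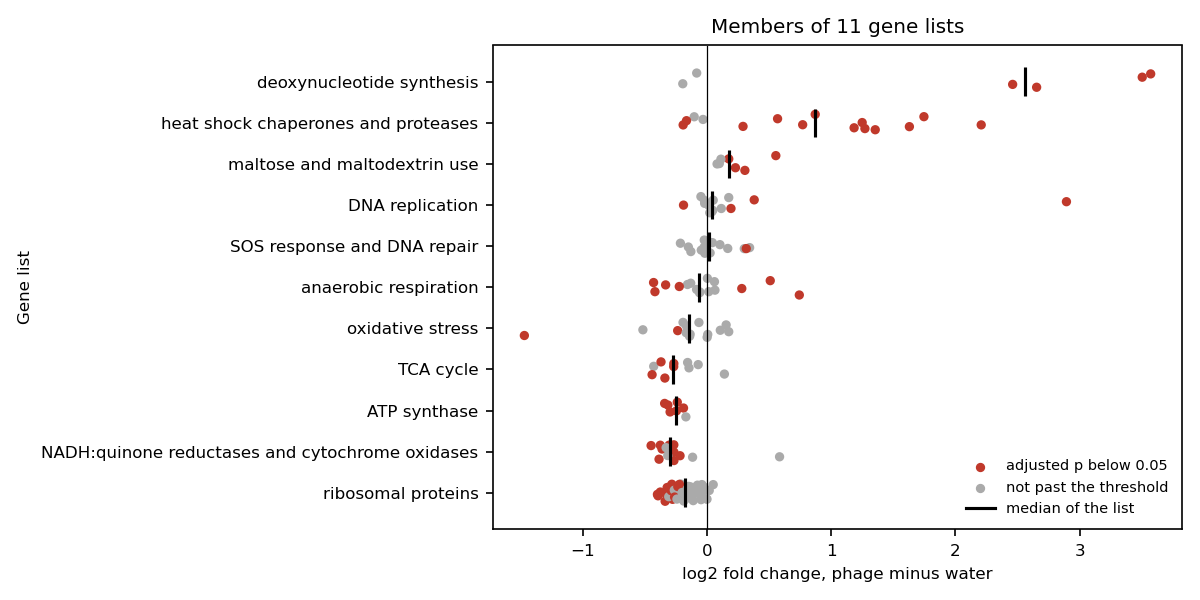
Log2 fold change (phage minus water, n = 3 each) of each tested member of 11 gene lists, with a line at the list's median and red for an adjusted p below 0.05; vertical scatter within a list carries no meaning. The medians are 2.56 for deoxynucleotide synthesis and 0.87 for heat shock, against -0.18 for ribosomal proteins and -0.30 for NADH:quinone reductases and cytochrome oxidases.

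The largest fall among the genes covered by the naming rule was in ahpC (VP_RS23210), for a subunit of alkyl hydroperoxide reductase, which removes peroxides. ahpC fell 2.77-fold, from 588 ± 75.4 to 212 ± 13.4 CPM (edgeR adjusted p = 7.38e-09). The next row, ahpF (VP_RS23215), was not called (log2 fold change -0.165, edgeR adjusted p = 0.14). In the oxidative stress list, ahpC and the regulator gene oxyR (1.18-fold) fell out of 14 members (camera adjusted p = 0.0313, and adjusted p = 0.367 with an estimated correlation; 2 fell adjusted over the list alone). The call of oxyR was lost without phage 1 (adjusted p = 0.0807) and without phage 2 (0.0603), and that of the list without water 1 (0.0669). VP_RS21945 fell 2.49-fold and VP_RS16740 1.71-fold, both listed without a symbol. aceE (VP_RS12215), for the first subunit of pyruvate dehydrogenase, fell 1.38-fold from 4860 ± 433 to 3522 ± 12.7 CPM. pdhR, for its repressor, fell 1.36-fold, a call lost without water 2 (adjusted p = 0.0799) and without phage 1 (0.0668). napH (VP_RS22270), whose symbol denotes a subunit of nitrate reduction, fell 1.52-fold. napG fell 1.41-fold, a call lost without phage 1 (0.0627) and without phage 2 (0.072). In the anaerobic respiration list, 3 of 16 members rose and 4 fell (camera adjusted p = 0.594, and the same counts adjusted over the list alone). napA (VP_RS20910), the periplasmic nitrate reductase gene, fell 1.35-fold, whereas narQ, for a nitrate sensor, rose 1.67-fold, dmsB 1.42-fold and hcp 1.22-fold. The count of falls in that list was 2 by DESeq2, 2 without water 2, 2 without phage 1 and 1 without phage 2.

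In the maltose and maltodextrin list, 4 of 7 members rose and 0 fell (median 0.18, camera adjusted p = 0.000421, and adjusted p = 0.248 with an estimated correlation; 5 rose adjusted over the list alone). malT (VP_RS22920), for the activator of the maltose genes, rose 1.47-fold and malQ 1.24-fold. The list had 2 rises without phage 2. The calls of malF (1.17-fold) and malG (1.13-fold) were lost without phage 2 (adjusted p = 0.104 and 0.217). That of malF was also lost without phage 1 (0.0943), and that of malG without phage 3, water 2 or water 3 (0.125, 0.107 and 0.0779). In pyrimidine synthesis, carA (1.26-fold) and carB (1.32-fold), for carbamoyl phosphate synthase, fell and pyrH, for UMP kinase, rose 1.24-fold, out of 9 members (camera adjusted p = 0.0214, and adjusted p = 0.291 with an estimated correlation; 1 rose and 5 fell adjusted over the list alone). Purine synthesis had a median of -0.11 over 11 members, of which edgeR called 0 over all genes (5 at an unadjusted p under 0.05, 1 by DESeq2) and 2 fell adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.582 with an estimated correlation). In glycolysis only gpmM, for phosphoglycerate mutase, was called of 8 members, 1.13-fold higher, and 1 rose adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.461 with an estimated correlation). The call of gpmM was lost without phage 1 (0.091) and without phage 2 (0.114). The pyrimidine list was not called without water 3 (0.0579). The purine list was not called without water 3 (0.176) or phage 3 (0.0723), and glycolysis without water 2, water 3, phage 2 or phage 3 (0.0723, 0.0579, 0.0533 and 0.143) or with median-of-ratios scaling (0.0522).

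The SOS response and DNA repair list, the response to DNA damage, did not pass (camera adjusted p = 0.953). recA had a log2 fold change of -0.02 ± 0.059 SE (565 ± 34.1 CPM with water and 556 ± 35.6 with phage) and lexA of -0.13 ± 0.071. The called member was recO, 1.25-fold higher of 15 tested, whose call was lost in each of the 6 fits that left out a library (log2 fold change 0.25 to 0.37), and 0 rose adjusted over the list alone. In the envelope stress list 2 of 11 members rose, rpoE (1.16-fold) and rseB (1.16-fold), with a camera adjusted p of 0.169 and 3 rises adjusted over the list alone. rpoE lost its call without water 2, water 3, phage 2 or phage 3 (adjusted p = 0.127, 0.0639, 0.0682 and 0.178), and rseB without phage 2 or phage 3 (0.0653 and 0.0572). pspA (0.23 ± 0.095) and the stationary phase sigma factor gene rpoS (0.18 ± 0.115) did not pass, but did so without water 1 (log2 fold change 0.34, adjusted p = 0.00254, and 0.30, adjusted p = 0.0405). In the list of RNA polymerase and sigma factors 2 of 8 rose, rpoD (1.16-fold) and rpoE, and 2 fell, rpoB and rpoC (1.12-fold each), with a camera adjusted p of 0.839 and the same counts adjusted over the list alone. rpoB and rpoC lost their calls without water 3 or any 1 phage library (adjusted p from 0.0613 to 0.217), and rpoD without phage 3 (0.0602).

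In the quorum sensing list luxS, for autoinducer-2 synthase, rose 1.27-fold and opaR, for the master regulator of high cell density, 1.16-fold, out of 5 members (camera adjusted p = 0.465; 2 rose and 1 fell adjusted over the list alone). opaR lost its call without water 2, water 3, phage 2 or phage 3 (adjusted p = 0.0821, 0.0809, 0.104 and 0.115). In the iron uptake list pvuA, for the vibrioferrin receptor, fell 1.33-fold and hutZ 1.3-fold of 7 members (camera adjusted p = 0.192; 3 fell adjusted over the list alone), and hutZ lost its call without water 3, phage 1 or phage 2 (0.104, 0.21 and 0.0733). Of 22 aminoacyl-tRNA synthetase genes 3 rose, argS (1.26-fold), cysS (1.17-fold) and tyrS (1.16-fold), with a camera adjusted p of 0.947. Of 11 members of the phosphotransferase system list, which also holds genes for related sugar enzymes such as treC, 2 rose, among them treC (1.19-fold). In that list 3 fell, fruB (1.17-fold), nagE (1.17-fold) and fruA (1.15-fold), with a camera adjusted p of 0.462. Without phage 1, fruA and nagE lost their calls (adjusted p = 0.067 and 0.0656). The counts in these 2 lists were the same adjusted over the list alone. Of 11 aromatic amino acid genes aroA rose 1.19-fold and aroB fell 1.14-fold (camera adjusted p = 0.465; 1 rose and 2 fell adjusted over the list alone), aroB losing its call without phage 1 (0.0964) or phage 2 (0.138). Of 8 sulfate assimilation genes cysI (1.16-fold) and cysN (1.18-fold) fell (camera adjusted p = 0.346; 1 rose and 2 fell adjusted over the list alone). cysI lost its call without water 3, phage 2 or phage 3 (0.0629, 0.0727 and 0.0519) and cysN without water 2, water 3, phage 1 or phage 3 (0.107, 0.0988, 0.224 and 0.0754). By edgeR, 0 members were called in the arginine (9 tested), histidine (7), branched-chain amino acid (11), methionine (8) and osmotic stress (6) lists, whose camera adjusted p ran from 0.537 to 0.93, and 0 adjusted over the list alone. At an unadjusted p under 0.05 these lists held 1, 0, 1, 3 and 0 members, and DESeq2 called 0.

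The virulence regulator gene toxR had a log2 fold change of -0.10 ± 0.061 SE (edgeR adjusted p = 0.318). The rows with the symbol tdh and a length of 570 bases, the thermostable direct haemolysin genes, had log2 fold changes of 0.15 ± 0.086 (VP_RS21465) and 0.04 ± 0.195 (VP_RS21755). Another row with this symbol, VP_RS22380, is 1032 bases long and had a log2 fold change of -0.12 ± 0.05; by its length it was not taken as a copy of the others. Lists with 1 to 3 tested members had no list test. In the porin list ompW rose (1 of 3), and 0 members were called in the lists for cold shock (3), haemolysins (3), pili (3), the cps locus (1), the polar flagellum (1) and chemotaxis (1) by edgeR and by DESeq2. At an unadjusted p under 0.05 there was 1 in the haemolysin list and 0 in the others. That member was the 1032-base row VP_RS22380, not a 570-base haemolysin row.

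Gene lists added after the data were examined covered secretion, motility and other functions by symbol. In fatty acid synthesis 7 of 16 members fell and 0 rose (median -0.17, camera adjusted p = 0.00163, and adjusted p = 0.82 with an estimated correlation), among them accC (1.3-fold), accB (1.24-fold) and fabB (1.26-fold). The other 8 added lists did not pass camera. In the directional form of fry, cell division passed (adjusted p = 0.000417) and fatty acid synthesis did not (0.112). The median log2 fold change of cell division was 0.01 and its largest, 2.17, was that of zipA. Its pass is thus no shift of the whole list, and the list was not tested without zipA. The mixed form of fry, for changes in either direction, was passed by cell division and fatty acid synthesis (1.25e-06 and 0.017). It was also passed by the flagellar (0.00572), RND efflux (0.000845) and pyruvate dehydrogenase (0.00058) lists. Type III secretion genes of the vsc, vcr and exs families had 1 rise of 31 (vscC, 1.4-fold, camera adjusted p = 0.843). DESeq2 did not call vscC (adjusted p = 0.0744), and its call was lost without water 1 (0.0952), phage 1 (0.113), phage 2 (0.126) or phage 3 (0.0586). A second set of type III effectors had 1 rise of 9 (vopD2, 1.16-fold, camera adjusted p = 0.646), whose call was lost without water 3 (0.0706) or phage 1 (0.147). By edgeR and DESeq2, type VI secretion genes had 0 calls of 22 (0.913) and type II secretion 0 of 11 (0.873), with 0 at an unadjusted p under 0.05. Of 27 type VI rows 22 passed the count filter, and of 37 rows of the vsc, vcr and exs families 31 did. The uncalled type VI log2 fold changes ran from -0.43 to 0.62, so the lack of calls does not exclude changes there. Flagellar genes had 1 rise of 52 (fliG, 1.2-fold, 0.873). RND efflux genes had 1 rise (vmeY) and 2 falls (vmeA and vmeB) of 19 (0.873). Cell division genes had 4 rises, among them zipA, ftsY (1.2-fold) and ftsE (1.22-fold), and 2 falls of 31 (0.748). The call of ftsE was lost without phage 1 (0.0544) or phage 2 (0.11). Pyruvate dehydrogenase and formate genes had 1 rise (adhE, for alcohol dehydrogenase, 1.26-fold) and 4 falls of 14, among them aceE, aceF and lpdA (0.494).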

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

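The settings below were planned before the data were examined, except leaving the 8 lead genes out of the scaling and all settings for genes of the added lists or named after their values were seen. Called genes numbered 599 with median-of-ratios scaling, 641 with upper-quartile scaling (51.6% of them higher, against 60.5% with TMM), 600 without a filter, 578 with a filter at 10 CPM, 598 without the 10 most abundant genes in the scaling, 597 without the 8 lead genes and 521 by DESeq2, against 603. In each of these and in every fit without 1 library, 0 of the calls shared with the 603 changed direction, and the median of all genes stayed within 0.1 of 0 on the log2 scale. Scaling sets most genes near 0 by design, and calls made in both fits could hardly reverse, so neither point tests the results strongly. Without 1 library, called genes ranged from 380 (without phage 1) to 755 (without water 1), higher genes from 263 to 423, lower genes from 114 to 332, genes at 2-fold from 51 to 59 and called lists from 9 to 11. Without phage 1, 376 of the 380 calls were among the 603, and without phage 2, 381 of 383; 120 genes were lower without phage 2. These fits have fewer libraries, and the cause of the lower counts than without phage 3 (480) was not tested. Called lists fell from 11 to 0 with an estimated correlation, which among them ranged from -0.022 (deoxynucleotide synthesis) to 0.573 (ATP synthase). The deoxynucleotide estimate lies below the preset 0.01, so a larger correlation does not account for that list's loss (camera adjusted p = 0.0629). With an estimated correlation camera also has far fewer degrees of freedom, set by the libraries and not the genes, which raises p in every list. How much of the loss in the other lists comes from their correlation was not tested. Called lists rose to 22 with the mixed form of fry, which asks whether members change in either direction. With its directional form they numbered 10. There ribosomal proteins (adjusted p = 0.0662), purine synthesis (0.155) and glycolysis (0.0608) did not pass, and DNA replication (0.00611) and envelope stress (0.0398) did. DNA replication had a median log2 fold change of 0.04 with ligA at 2.89, and was not tested without ligA.

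The replicate numbers were not taken as pairs: libraries with the same number had deviation correlations of -0.03, 0.15 and -0.14, and water 1 correlated best with phage 3 (0.21). With the number as a block, 560 genes were called, 549 of them among the 603; groL (VP_RS16645), malG, recO and pgl were not (adjusted p = 0.0501, 0.0555, 0.0613 and 0.0632), and 2 anaerobic respiration genes fell, against 4. Alternatives for a pseudocount apply to normalised values and were not run. The share of ribosomal and transfer RNA gave no value beyond the 5S rows, so leaving out libraries was not run for it. DESeq2 gave no adjusted p for 571 genes and did not call dnaA, malG, opaR, recO and vscC (0.0526, 0.0875, 0.0548, 0.0866 and 0.0744). In simulated data edgeR recovered 40.8% of changes of 0.3 on the log2 scale, and no other depth or number of changed genes was run.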

Other observations

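The tests of phage reads, scaling, nrdR, handling, stock liquid and counts taken up by risen genes were chosen after the results were seen, as were the genes and rows named in the next paragraph.

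Several runs of consecutive rows, most of them outside the gene lists, were called in one direction. menH, menB, menC and menE, for menaquinone synthesis, rose by 0.70, 0.23, 0.20 and 0.56 on the log2 scale, and menC lost its call without phage 1 (adjusted p = 0.067) or phage 2 (0.144). mazG and relA, for a nucleotide pyrophosphohydrolase and the (p)ppGpp synthetase, rose 1.58-fold and 1.54-fold, relA from 850 ± 30.4 to 1306 ± 5.64 CPM (SD, n = 3 each). era and rnc, for a ribosome assembly GTPase and RNase III, rose 1.37-fold and 1.33-fold. A run of 8 rows that holds neuC and neuB, symbols of sialic acid synthesis, rose by 0.23 to 0.42, and neuB lost its call without water 3 (adjusted p = 0.0599) or phage 1 (0.0854). zwf, pgl and gnd, for the oxidative pentose phosphate pathway, fell 1.23-fold, 1.18-fold and 1.27-fold, and pgl lost its call without water 3, phage 1, phage 2 or phage 3 (adjusted p = 0.161, 0.0613, 0.087 and 0.134). Within the ribosomal protein list, 11 consecutive genes from rpsJ to rpsQ fell, with log2 fold changes of -0.40 to -0.23. Of 33 tested rows of 70 to 95 bases without a symbol, 8 rose and 0 fell. The table holds 152 such rows, and several of the risen ones had few counts with water and passed the count filter through their phage counts, so these numbers do not compare short rows with other genes. The largest of the rises was VP_RS12940 (85 bases), from 3.51 ± 0.944 to 36.3 ± 4.85 CPM (10-fold). These rows took 0.0435% ± 0.00524 of counts with water and 0.0529% ± 0.00306 with phage (exact permutation p = 0.1, the smallest possible, n = 3 each).

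Joint transcription of neighbouring genes is a candidate explanation for such runs. In the order of the table, 180 neighbouring pairs were called in one direction, against a median of 42 and a highest value of 63 in 1000 shuffles of the tested genes. Pairs called in opposite directions numbered 26, within the shuffled range of 23 to 61. There were 36 runs of at least 3 genes, 22 higher and 14 lower. Reads that cross from a gene into the next row, with the strand setting unknown, would give such pairs as well.

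Chance in the grouping of the libraries can be judged only roughly, since 3 against 3 makes 10 splits and the share cannot go under 0.1. The real split alone (1 of 10) reached its count in each case: 603 called genes (365 higher, 238 lower, 56 at 2-fold) against a highest value of 0 in the other splits by edgeR, where 57 to 220 genes had an unadjusted p under 0.05 (1056 in the real split). Each of the other splits mixes water and phage libraries, so the difference between the groups widens the spread within its sides. A count of 0 there therefore says little about chance. DESeq2 was not run on the splits. For called lists it was 11 against a highest of 8, reached by the split that puts water 1 with phage 2 and phage 3. That split, like each of the mixed ones, puts 2 phage libraries on one side. The cause of its list calls was not tested.

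The rise of nrdA, nrdB, yfaE, nrdD, nrdG, zipA and ligA kept its size in the settings run. Over 10 settings of scaling, filter, tool, block and left-out libraries, the lowest log2 fold change of these genes was 2.13 and the highest 3.59. Median-of-ratios was the only other scaling method among them, so they test scaling weakly. The share of raw counts, 0.197% with water and 1.49% with phage (n = 3 each), uses no TMM factor, so the choice of factor does not make the rise. A lower transcript level of nrdR, for the repressor of ribonucleotide reductase genes, is argued against by its log2 fold change of -0.08 ± 0.092 SE, though the activity of its protein was not measured. It stays open whether reads of the phage's own genes were counted on host genes, since many lytic phages carry reductase or ligase genes and the sequence of VpP2326 was not used here. The 7 genes lie in 3 runs of rows, and these tables cannot tell such reads from host transcripts. A host response to the phage may also account for the rise, as an untested hypothesis.

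The rise of heat shock chaperone and protease genes was larger than the differences between libraries of a group, whatever their source. The gap between the lowest phage and the highest water library mean was 0.66 on the log2 scale, against a largest range within a group of 0.22. A difference in handling common to all phage libraries has no such bound. The list was called on these same libraries, so the gap describes the rise and does not test it. Whether the liquid of the phage stock, rather than the phage, set off the rise stays open, because 0 libraries received the phage stock's liquid without phage. A response to infection is therefore only a candidate explanation.

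The fall of ribosomal protein, ATP synthase, respiratory and TCA cycle genes covers 84 genes, of which 41 were called lower and 0 higher, with a median of -0.23; 27 were called lower without phage 1 and 27 without phage 2. Genes that rose took 12.2% ± 0.181 of counts with water and 16.9% ± 0.236 with phage (n = 3 each). With all risen genes left out of the scaling the median was -0.21, against 0.018 for all genes and a largest range within a group of 0.13, so counts taken up by these genes do not account for the fall. A trend with transcript abundance is argued against as well. In 10000 random lists matched on mean expression, the medians centred on -0.022 and the lowest was -0.098. The 84 genes lay at percentile 0 of these lists. The pooled lists were all called lower in these same data, so that percentile is no test of the fall itself. Random lists of single genes lack the correlation within operons, so they understate the spread of such a list. Slower growth, or the liquid of the phage stock, may lower these genes too, and the design cannot tell these from an effect of the phage.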
